A study of Macaca mulatta with 12 samples.

How the data were processed

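Total RNA of 12 rhesus macaque samples was hybridised to 1 Affymetrix rhesus array each, 3 arrays for each of 4 cell populations, after biotin labelling by a one-cycle protocol, per the labels' protocols. The deposited table holds log2 expression values per probe set, summarised by the authors with RMA, per the submitters' processing notes. The RMA version, the software and the probe set definition were not given in the sources used here. That the scale is log2 was taken from the values, which had array medians between 5.012 and 5.098 on all 12 arrays. RMA corrects background and makes arrays alike in distribution, so a difference shared by most genes would be reduced, and differences of genes near the background are understated. No detection calls were used. The table held 52865 features, and 99 control features were left out, leaving 52766 probe sets. Background was judged from 42 bacterial poly-A control probe sets (median 3.75, 90th percentile 4.26). No column belonged to a sample outside the series, and no pair of arrays held identical values. The number of arrays limits the precision, and signal near the background carries little information.

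Probe sets were named from the platform annotation given for the series: 24956 had 1 symbol, 361 several and 27449 none. Symbols of 24616 probe sets matched a reference gene table of the assembly T2T-MMU8v2.0, none needed renaming, and the table was used only for names and for the chromosome and order of genes, which rested on its positions. This assembly is not the build of the array, and none of its coordinates is printed. Probe sets with several symbols were left unnamed, and 1691 probe sets with provisional LOC symbols were left out of the genes named. Per gene, the probe set with the highest mean over the 12 arrays was used, giving 14132 genes.

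Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with group means over all 12 arrays, 8 residual and 3.69 prior degrees of freedom). P-values are two-sided and adjusted by the Benjamini-Hochberg method over all probe sets. A probe set was called at an adjusted p under 0.05 and a difference of at least 2-fold. The labels give no batch, so no covariate was fitted. Comparisons were each parthenogenetic line against ORMES-22, the parthenogenetic lines against each other, fibroblasts against ORMES-22, and each ES line against the mean of the other 2. Chance sharing under shared controls was simulated with 100 sets of unchanged groups.

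The comparisons, 15 gene lists, the rule for named genes and all alternatives save 3 were fixed before the data were examined. The lists were paternally and maternally expressed imprinted genes of humans (some imprinted only in some tissues), pluripotency, fibroblast and matrix, endoderm, mesoderm, neuroectoderm, trophoblast, X inactivation, Y-linked, antigen presentation, cell cycle, DNA methylation and imprint maintenance, germ cell and other skin cell genes. No measured gene was in more than 1 list. Lists were tested with camera (preset correlation 0.01, and an estimated correlation) and fry, and 65 list tests were adjusted together. Fry asks only whether the genes of a list changed, without setting them against other genes. Adjusted p-values of lists are those of camera with the preset correlation unless another test is named. Named genes were the 10 largest increases and 10 largest decreases per comparison among called genes whose replicate values did not overlap between the groups compared. To these were added every imprinted gene called between ES lines, up to 4 called genes of each other list or the 2 with the largest difference, the Y-linked and X inactivation genes measured, and OSBPL1A.

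The methods were tested on simulated data. Of changed probe sets, limma called 58.2% at a log2 change of 1, 98.5% at 2 and 100% at 3 for rPESC-2 against ORMES-22. The shares were 37.3%, 98.5% and 100% for ORMES-9 against ORMES-22, 49.3%, 100% and 100% for ORMES-9 against rPESC-2, and 43.3%, 100% and 100% for fibroblasts against ORMES-22. Each share is of 66 or 67 changed probe sets, and at most 2 unchanged ones were called. Every simulated group had the same spread, so false calls under unequal spread were not tested. In the data ORMES-22 had the widest median spread (SD 0.127). Of 200 random lists of 14 genes, camera with the preset correlation placed 3.5% under a p of 0.05. The simulated genes varied independently, so this does not test lists whose genes vary together. The estimated correlation was 0.22 in the endoderm and 0.19 in the matrix list.

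Alternatives were a fit of only the groups compared or only the 9 ES arrays, the replicate letter as a block, dim probe sets left out, array medians subtracted, quantile normalisation, trended and robust moderation, array weights, no or a 3-fold minimum, genes in place of probe sets, other ways to choose a gene's probe set, the mean of the 3 ES lines as reference and each array left out in turn. The omission of ORMES-22 replicate A together with rPESC-2 replicate B, the omission of each ES array from the sharing with exchanged lines, and a count of other probe sets of named genes above the background of 4.26 in place of a log2 signal of 6 (highest mean of an ES line) were added after seeing the data.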

Results

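Gene expression was measured on 12 single-sample Affymetrix rhesus macaque arrays, 3 for each of 4 cell populations. ORMES-22 is an embryonic stem (ES) cell line from an embryo made by in vitro fertilisation, and so carries a maternal and a paternal genome. rPESC-2 and ORMES-9 are parthenogenetic ES cell lines, which come from an egg that developed without fertilisation and carry maternal genomes only. rPESC-2 is described as heterozygous and ORMES-9 as homozygous. For ORMES-9 the labels conflict: the sample descriptions and the series design call it a homozygous parthenote, while its source field names a fertilised embryo, and it was analysed as parthenogenetic. Adult skin fibroblasts were the somatic control. The ES lines are labelled female and the fibroblasts male, so sex differed between fibroblasts and every ES line. ES cells were grown on mouse embryonic fibroblast feeder cells, and the RNA came from colonies picked as undifferentiated at passages 18, 21 and 19 for ORMES-22, 16, 10 and 16 for rPESC-2 and 13, 14 and 16 for ORMES-9 (replicates A, B and C).

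The values were log2 expression summaries of 52766 probe sets, and the medians of the 12 arrays lay between 5.012 and 5.098. Each array was one of 3 that the labels call biological replicates of a line, and p-values therefore measure the spread between cultures or arrays of one line, not between lines or animals. There was 1 biparental ES line, so its parental origin and every other property of that line differ together from the parthenogenetic lines. The number of arrays limits the precision of every value. Across probe sets, which are not independent replicates, the fibroblast arrays correlated with each other at 0.9957 to 0.9968 and with no ES array above 0.8812. The rPESC-2 arrays correlated with each other at 0.9937 to 0.995 and the ORMES-9 arrays at 0.9948 to 0.9956. ORMES-22 replicates B and C correlated at 0.9928. ORMES-22 replicate A correlated with them at only 0.9844 and 0.9855, below its correlation of 0.9896 with rPESC-2 replicate A, and 316 of 14132 genes were at least 2-fold higher and 179 at least 2-fold lower in it than in the mean of replicates B and C. This array widened the spread of ORMES-22, so counts without it are given beside those it moves most.

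The comparison of rPESC-2 with ORMES-22 addressed which genes differ when the paternal genome is missing, in the heterozygous parthenogenetic line. Transcripts of several imprinted genes that are expressed from the paternal copy were far lower in rPESC-2. SNRPN, which encodes a splicing protein and lies in the Prader-Willi region, was 129-fold lower (log2 −7.01, SE 0.12, adjusted p = 2e-11), at 5.79 ± 0.14 against 12.80 ± 0.22 in ORMES-22 (log2, SD, n = 3 each). The imprinted transcription factor genes PLAGL1 and PEG3 were 9.07-fold and 5.55-fold lower (adjusted p = 0.0017 and 9.2e-05), PLAGL1 15.3-fold without ORMES-22 replicate A. Of 10 endoderm genes measured, 4 rose (camera adjusted p = 4e-04 for the list, and adjusted p = 0.28 with an estimated correlation), led by the transcription factor SOX17 at 7.54-fold (log2 2.92, SE 0.35, adjusted p = 0.00053), whose other probe set gave an uncalled 0.70.

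In limma, 656 of 52766 probe sets passed an adjusted p of 0.05 and a 2-fold difference, 406 higher and 250 lower in rPESC-2, naming 326 genes. Without ORMES-22 replicate A the count was 1493, and a fit of only the 6 arrays compared gave 332. The 10 genes with the largest increase were DCTD, DERA, GCA, SH3YL1, DKK1, GZMA, ZBTB33, C1H1orf115, SOX17 and PIGP, between 59-fold for DCTD and 7.09-fold for PIGP. DCTD, a deoxycytidylate deaminase of pyrimidine nucleotide metabolism, differed by 5.88 on the log2 scale (SE 0.42, adjusted p = 1e-05), and 3 other DCTD probe sets by 1.21, 3.29 and 4.04. DERA, an aldolase that splits deoxyribose phosphate, differed by 5.48 (SE 0.60, adjusted p = 0.00032), and GCA, which encodes the calcium-binding protein grancalcin, by 5.06 (SE 0.24, adjusted p = 3.3e-07). DKK1, a secreted inhibitor of WNT signalling, was 9.14-fold higher (SE 0.18 on the log2 scale, adjusted p = 1.8e-06). The differences were larger without ORMES-22 replicate A, 6.58 for DCTD, 90.5-fold in place of 44.5-fold for DERA, and on the log2 scale 4.73 in place of 3.67 for SH3YL1, 3.77 in place of 3.14 for GZMA and 3.65 in place of 3.04 for C1H1orf115. SH3YL1 was 3.05 without ORMES-22 replicate C and C1H1orf115 2.37 without ORMES-22 replicate B. The 10 largest decreases were in SNRPN, THBS1, MEST, AKAP7, SPATS2L, PLAGL1, CSGALNACT2, MECOM, ACTC1 and PEG3. THBS1, the matrix glycoprotein thrombospondin-1, was 34.4-fold lower (log2 −5.11, SE 0.43, adjusted p = 4e-05), and of 4 other THBS1 probe sets, those with −2.49 and −4.06 were called and those with −0.65 and −0.06 were not. The other CSGALNACT2 probe set above background gave an uncalled −0.10. ACTC1, cardiac alpha-actin, was 5.58-fold lower (log2 −2.48, SE 0.28, adjusted p = 0.00034).

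Of 29 paternally expressed imprinted genes listed, 14 were measured. Of these, 6 were lower in rPESC-2, 1 was higher and 7 were not called (NDN, IGF2, MKRN3, NPAP1, L3MBTL1, DIRAS3 and INPP5F), with the same counts adjusted over the list alone. The list was lower than other genes (camera adjusted p = 1.7e-05, and adjusted p = 0.022 with an estimated correlation). Besides SNRPN, PLAGL1 and PEG3, the lower genes were MEST (log2 −4.95, SE 1.02, adjusted p = 0.017), MAGEL2 (−1.89, SE 0.28, adjusted p = 0.0022) and SGCE (−1.49, SE 0.21, adjusted p = 0.0017). A second SNRPN probe set differed by −4.80. MEST was 3.71, 8.95 and 3.86 in rPESC-2 replicates A, B and C, and its call was lost without ORMES-22 replicate B, rPESC-2 replicate A or rPESC-2 replicate C (−5.04, −4.05 and −4.12), while the difference was −6.67 without rPESC-2 replicate B. PLAGL1 was 5.40 in ORMES-22 replicate A and 7.65 in both other replicates, and its difference was −3.18 with and −3.93 without replicate A. DLK1, a membrane protein of the Notch ligand family, was higher by 1.44 (SE 0.36, adjusted p = 0.041). Its call was lost without ORMES-22 replicate B (1.24) or C (1.19) and without rPESC-2 replicate A (1.41), B (1.54) or C (1.37). When only the 6 arrays compared were fitted, 2 of the list were called lower.

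**Figure D1:**
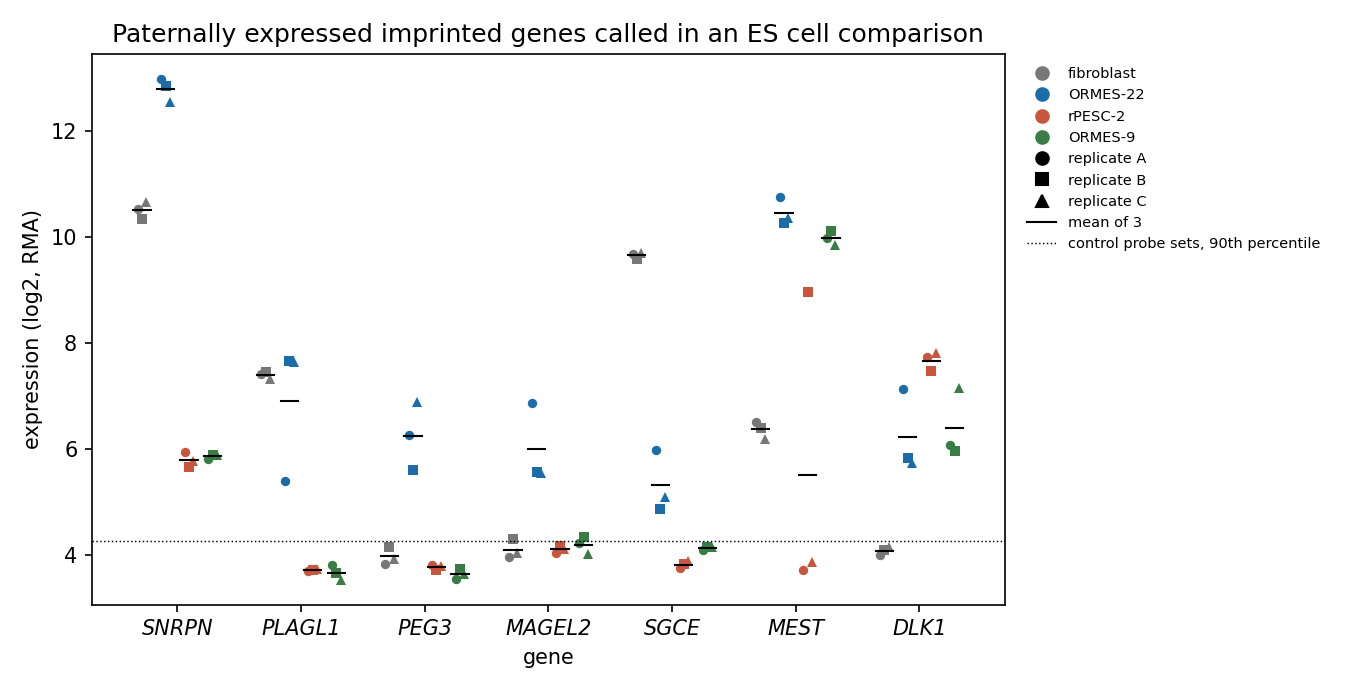
Expression (log2, RMA) of the 7 paternally expressed imprinted genes called in a comparison between ES lines, by gene, with 1 point per array in colours for the 4 populations and shapes for replicates A, B and C, horizontal bars for means of 3 and a dotted line at the 90th percentile of the bacterial control probe sets (4.26). SNRPN was 12.80 in ORMES-22, 5.79 in rPESC-2 and 5.86 in ORMES-9, and MEST was high in 1 of the 3 rPESC-2 arrays.

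None of 17 measured maternally expressed imprinted genes (of 23 listed) was called in rPESC-2 against ORMES-22 by limma (6 at an unadjusted p under 0.05; 0 adjusted over the list alone; camera adjusted p = 0.23). Of 10 endoderm genes measured (of 13), 4 rose and none fell by limma (also adjusted over the list alone): SOX17, GATA6 (log2 2.78, SE 0.31), CER1 (2.21, SE 0.30) and FOXA2 (1.89, SE 0.18), 3 transcription factors and a secreted inhibitor of Nodal and BMP signals. The list was higher than other genes (camera adjusted p = 4e-04), but not with an estimated correlation (adjusted p = 0.28) or without ORMES-22 replicate A (adjusted p = 0.051). Fry gave an adjusted p = 0.0016 for this list and 0.014 for the fibroblast and matrix list. Of 23 fibroblast and extracellular matrix genes (of 29), 3 fell (4 adjusted over the list alone), with a camera adjusted p = 0.00019 and an adjusted p = 0.37 with an estimated correlation. They were the collagen cross-linking enzyme LOX (log2 −2.32, SE 0.45), COL6A3 (−1.84, SE 0.32) and the mesenchymal transcription factor TWIST1 (−1.80, SE 0.24). LOX lost its call without ORMES-22 replicate B (−1.98) or rPESC-2 replicate B (−2.30) and was −3.05 without ORMES-22 replicate A, and 6 genes of this list were lower without ORMES-22 replicate A.

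In the other lists few genes changed in rPESC-2 against ORMES-22, and none had a camera adjusted p under 0.05. Pluripotency genes (18 measured of 28) held 1 higher gene, the TGF-beta family member GDF3 (1.23, SE 0.24, camera adjusted p = 0.35 for the list), whose call was lost without ORMES-22 replicate C (0.95) or rPESC-2 replicate B (1.19). Of 12 mesoderm genes (all of the 12 listed), ACTC1 was lower (list adjusted p = 0.82; 1 higher and 2 lower adjusted over the list alone). Of 14 antigen presentation genes (of 20), the class I gene MAMU-B was higher (1.33, SE 0.13) and MAMU-E 2.01-fold lower (SE 0.14 on the log2 scale; list adjusted p = 0.57), the latter not without ORMES-22 replicate A (−0.87) or rPESC-2 replicate B (−0.86). Of 9 germ cell genes (of 12), the receptor gene KIT was higher (1.51, SE 0.28; list adjusted p = 0.82). This list had a median of −0.05 and a mean of 0.19. By limma, none was called among 6 neuroectoderm (of 13; 3 at an unadjusted p under 0.05, adjusted p = 0.82; 1 lower adjusted over the list alone), 11 trophoblast (of 13; 5, adjusted p = 0.14), 16 cell cycle (of 23; 5, adjusted p = 0.066), 10 DNA methylation and imprint maintenance (of 15; 3, adjusted p = 0.41) and 15 other skin cell genes (of 18; 1, adjusted p = 0.82). In these lists the largest differences were PAX6 at −1.29, TFAP2C at −1.23, TOP2A at 0.66, TET1 at 1.10 and TYR at −0.20. Apart from neuroectoderm, mesoderm and the matrix list, the counts adjusted over the list alone were the same. Without ORMES-22 replicate A the trophoblast list passed (camera adjusted p = 0.043), without ORMES-22 replicate B the pluripotency list (0.038), and without rPESC-2 replicate A the cell cycle list (0.039). These values rest on the preset correlation. With an estimated correlation over all arrays, camera gave these lists an adjusted p of 0.79, 0.79 and 0.77.

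The comparison of ORMES-9 with ORMES-22 asked the same of the homozygous parthenogenetic line. SNRPN was 123-fold lower in ORMES-9 (log2 −6.94, SE 0.12, adjusted p = 1.5e-11), at 5.86 ± 0.05 (SD, n = 3), and PLAGL1 and PEG3 were 9.39-fold and 6.11-fold lower (adjusted p = 0.00095 and 3.8e-05), PLAGL1 15.8-fold without ORMES-22 replicate A. CAVIN2, a component of caveolae, was 35.2-fold lower (log2 −5.14, SE 0.21, adjusted p = 4.1e-08) and the membrane receptor DCBLD2 27.8-fold lower (−4.80, SE 0.17, adjusted p = 1.2e-08), although the other, dimmer DCBLD2 probe set gave an uncalled 0.24. RAB25, a small GTPase of epithelial membrane traffic, rose 11.4-fold (3.51, SE 0.27, adjusted p = 1e-05). SOX17, FOXA2 and GATA6 rose as in rPESC-2.

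In limma, 831 probe sets were called in ORMES-9 against ORMES-22, 499 higher and 332 lower, naming 436 genes, and 1284 without ORMES-22 replicate A. DCTD (42.2-fold), DERA (42.1-fold), GCA (32.8-fold) and SH3YL1 (11.6-fold) led the higher genes. These were 68.3-fold for DCTD, 85.5-fold for DERA and 24.1-fold for SH3YL1 without ORMES-22 replicate A, and SH3YL1 was 7.54-fold without ORMES-22 replicate C. They were followed by RAB25, WFDC2 (9.37-fold, but −0.11 on the log2 scale in another probe set), the lysosomal acid lipase LIPA (9.2-fold), THEMIS2 (8.82-fold), C1H1orf115 (8.66-fold, but 13.2-fold without ORMES-22 replicate A and 5.42-fold without B) and VSTM2A (8.46-fold, with an uncalled 0.53 on the log2 scale in another probe set). The lower genes after SNRPN, CAVIN2 and DCBLD2 were ZNF22 (23.6-fold), RWDD3 (17.3-fold), the transmembrane protein gene TMEFF2 (12.8-fold), ANKRD1 (12.5-fold), the mitochondrial ribosomal protein gene MRPL54 (12-fold), ERI2 (10.7-fold) and AKAP7 (9.7-fold). TMEFF2 was 7.45-fold and ANKRD1 20.4-fold lower without ORMES-22 replicate A, and TMEFF2 19.5-fold lower without ORMES-22 replicate B. Adjusted p-values of these 20 genes ran from 1.5e-11 for SNRPN to 0.0052 for SH3YL1.

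Of the 14 paternally expressed imprinted genes, 5 fell and none rose in ORMES-9 (also adjusted over the list alone): SNRPN, PLAGL1 (log2 −3.23, SE 0.45, and −3.98 without ORMES-22 replicate A), PEG3 (−2.61, SE 0.23), MAGEL2 (−1.80, SE 0.28) and SGCE (−1.18, SE 0.21). The list was lower than other genes (camera adjusted p = 1.7e-05, and adjusted p = 0.022 with an estimated correlation). SGCE was −0.85 and not called without ORMES-22 replicate A, and with only the 6 arrays compared 2 genes of the list were called. MEST differed by −0.47 (SE 1.02, adjusted p = 0.87) and DLK1 by 0.17 (SE 0.36, adjusted p = 0.87). The SE of MEST was set largely by rPESC-2, a line outside this comparison (SD 2.987, against 0.261 in ORMES-22 and 0.131 in ORMES-9). NDN was not called through the probe set chosen for it (−0.30, SE 0.15), while another NDN probe set was lower by a called amount (−1.39, adjusted p = 3.11e-04). In the parthenogenetic lines PLAGL1, PEG3, MAGEL2 and SGCE all had means under 4.26, the 90th percentile of bacterial control probe sets on these arrays, so their sizes depend on the background of the arrays. Of the 17 maternally expressed genes, only ZNF597 was called in ORMES-9 (1.46, SE 0.16, adjusted p = 0.00018; the same adjusted over the list alone), and the camera adjusted p of the list was 0.58, with a median of −0.10 and a mean of 0.04. OSBPL1A, remembered as a gene that the study chose from these samples and so not independent evidence, differed by −0.10 in rPESC-2 and −0.25 in ORMES-9 (SE 0.15 each; adjusted p = 0.75 and 0.42).

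Of 10 endoderm genes, 3 rose in ORMES-9 (4 adjusted over the list alone): SOX17 (log2 2.37, SE 0.35, and an uncalled 0.73 in its other probe set), FOXA2 (2.33, SE 0.18) and GATA6 (2.14, SE 0.31). The camera adjusted p was 0.00086 (adjusted p = 0.28 with an estimated correlation), and 0.051 without ORMES-22 replicate A. Fry gave an adjusted p = 0.0029 for this list and 0.0079 for the fibroblast and matrix list. Of 23 fibroblast and matrix genes, TWIST1 (−2.67, SE 0.24) and the galectin LGALS1 (−1.63, SE 0.35) fell, 7 fell adjusted over the list alone, and 12 had an unadjusted p under 0.05. The camera adjusted p was 2.1e-05 (adjusted p = 0.28 with an estimated correlation). LGALS1 lost its call without ORMES-22 replicate B (−1.62), ORMES-9 replicate A (−1.67) or ORMES-9 replicate B (−1.52), and without ORMES-22 replicate A 5 genes of the list were lower. Of 18 pluripotency genes, 3 rose: PRDM14 (1.56, SE 0.32), the signalling factor NODAL (1.42, SE 0.34) and GDF3 (1.29, SE 0.24). PRDM14 lost its call without ORMES-9 replicate A (1.41) or B (1.52), and NODAL without ORMES-22 replicate A (1.16) or C (1.14) or ORMES-9 replicate A (1.32) or B (1.36). The list's camera adjusted p was 0.21, 0.039 without ORMES-22 replicate B, and 0.79 with an estimated correlation over all arrays.

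Single genes of 4 further lists changed in ORMES-9 against ORMES-22. They were ACTC1 of the mesoderm list (−2.24, SE 0.28; list adjusted p = 0.73), the thymidylate synthase gene TYMS of the cell cycle list (−1.13, SE 0.08; 0.99), KIT of the germ cell list (1.51, SE 0.28; 0.84) and the endothelial receptor gene TEK of the other skin cell list (−2.29, SE 0.21; 0.58). For the cell cycle list camera gave a rise and fry a fall around a median of 0.03. By limma, none was called among neuroectoderm (2 at an unadjusted p under 0.05, adjusted p = 0.9; 1 adjusted over the list alone), trophoblast (1, adjusted p = 0.68), antigen presentation (5, adjusted p = 0.57) and DNA methylation genes (1, adjusted p = 0.88). The largest differences there were PAX6 at −1.17, TEAD4 at −0.72, MAMU-E at −0.88 and TET2 at 0.33. Apart from endoderm, matrix and neuroectoderm, counts adjusted over the list alone were the same.

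**Figure D2:**
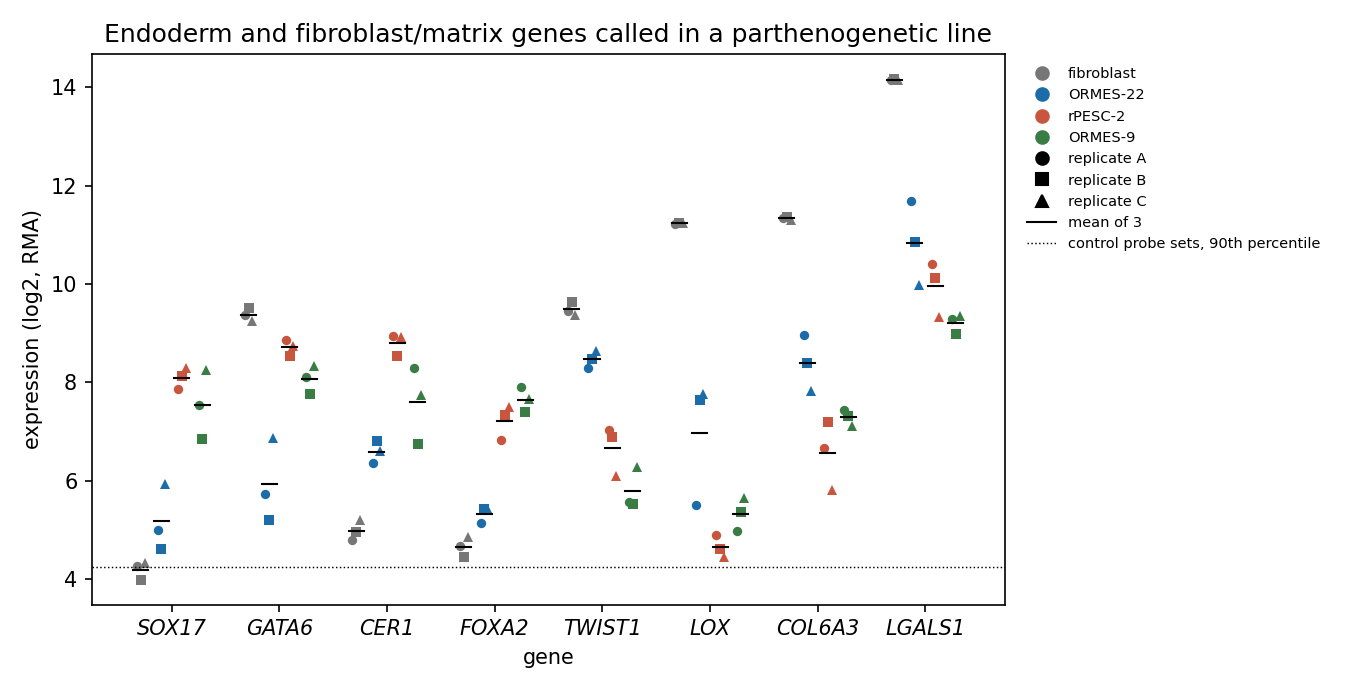
Expression (log2, RMA) of the endoderm and the fibroblast and matrix genes called in a parthenogenetic line against ORMES-22, by gene, with 1 point per array, bars for means of 3 and a dotted line at the 90th percentile of the bacterial control probe sets (4.26). SOX17 differed by 2.92 in rPESC-2 and 2.37 in ORMES-9, and TWIST1 by −1.80 and −2.67, each against ORMES-22.

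Probe sets that changed the same way in both parthenogenetic lines were counted because a missing paternal genome is common to them. DCTD, DERA, GCA, SH3YL1 and C1H1orf115 were among the 10 largest increases in both lines, and SNRPN and AKAP7 among the 10 largest decreases in both. In all, 274 probe sets (115 genes) were called with the same sign in both, 176 higher and 98 lower, while 9 that were higher and 3 that were lower in rPESC-2 were called with the opposite sign in ORMES-9. Without ORMES-22 replicate A there were 654 with the same sign, and with only the groups compared 146. Of the 5 paternally expressed genes lower in ORMES-9, each was also lower in rPESC-2.

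Both comparisons used the same ORMES-22 arrays. In 100 simulations of unchanged groups against shared controls, no probe set was called in both. With nothing changed, hardly any call could arise, and every group was given the same spread. This count therefore cannot say how much of the sharing comes from the shared controls. Independent lists as long as those called would share 3.84 higher and 1.57 lower probe sets. Over all probe sets the differences correlated at 0.57 (simulated 0.5, highest 0.515), 71.6% had the same sign (simulated 66.7%, highest 67.1%), and the covariance was 0.0622 (simulated 0.00899), a difference of 0.0532. The 3 control arrays cannot be split into groups of at least 2, and part of the excess may come from the shared controls. With the lines exchanged, 261 probe sets (98 genes) were called the same way in ORMES-22 and rPESC-2 against ORMES-9, and 174 (56 genes) in ORMES-22 and ORMES-9 against rPESC-2. Without ORMES-22 replicate A, a fit chosen after seeing the data for the exchanged lines, these counts were 248 and 273, against 654 for the pair of parthenogenetic lines. Beside the count with ORMES-9 in the place of ORMES-22, that of the parthenogenetic pair was lower without ORMES-22 replicate B (211 against 276) or C (241 against 277). It was also lower without rPESC-2 replicate B (213 against 255) or C (235 against 252) or ORMES-9 replicate A (222 against 263) or C (248 against 257). It was barely higher without rPESC-2 replicate A (249 against 248) or ORMES-9 replicate B (243 against 241). How the sharing of that pair stood to that of the other pairs thus depended on single arrays.

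**Figure D3:**
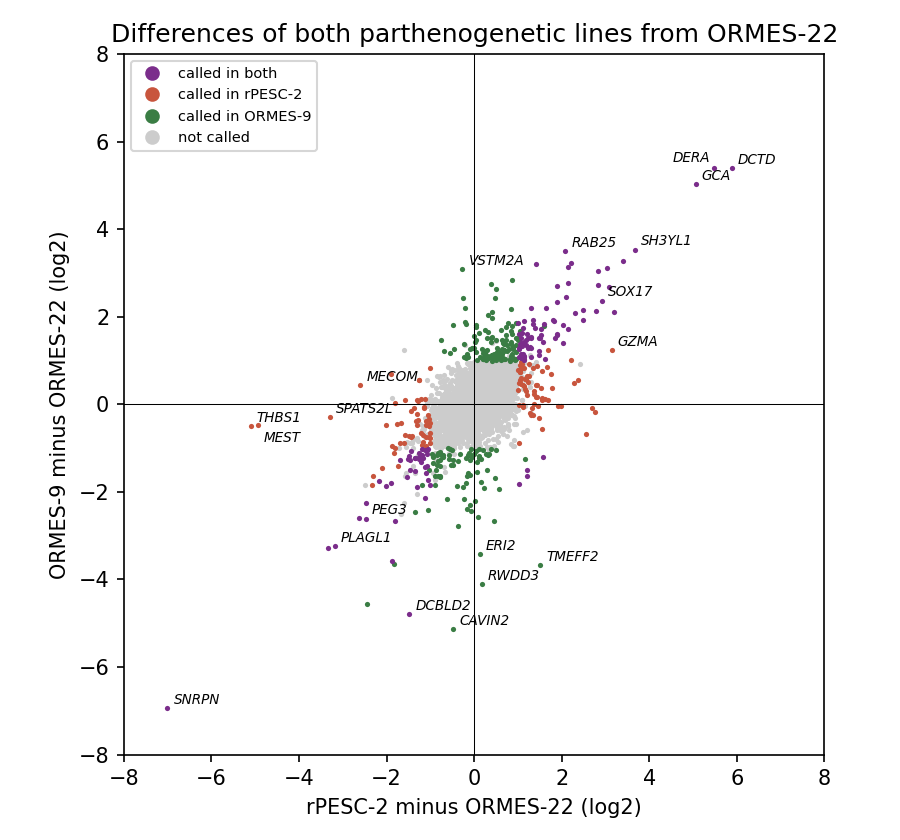
Log2 difference of each gene in rPESC-2 minus ORMES-22 (horizontal) and in ORMES-9 minus ORMES-22 (vertical), with 1 point per gene coloured by whether it was called in both comparisons, in 1 of them or in neither. SNRPN lies at −7.01 and −6.94, and DCTD at 5.88 and 5.40 (6.58 and 6.09 without ORMES-22 replicate A).

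The comparison of ORMES-9 with rPESC-2 set the homozygous against the heterozygous parthenogenetic line. THBS1 was 24.4-fold higher in ORMES-9 (log2 4.61, SE 0.43, adjusted p = 6.5e-05), but its 4 other probe sets gave 3.55, 1.77 and, not called, −0.20 and −0.11. TMEFF2 was 36.5-fold lower (−5.19, SE 0.49, adjusted p = 7.2e-05). CAVIN2 was 25.3-fold lower (−4.66, SE 0.21, adjusted p = 1.1e-07) and RWDD3 19.5-fold lower (−4.28, SE 0.16, adjusted p = 3.1e-08). The imprinted gene MEST was 22.2-fold higher (4.47, SE 1.02, adjusted p = 0.025). Its difference was 6.20 without rPESC-2 replicate B, and 3.57 and 3.65, not called, without A or C. The pair of lines differed at 650 probe sets in limma, 287 higher and 363 lower in ORMES-9, naming 324 genes. The further higher genes were VSTM2A (10.2-fold), the transcription factor MECOM (8.17-fold), SPATS2L (8.04-fold), the ephrin receptor EPHA1 (7.12-fold, with 3.37, 3.32 and an uncalled 0.42 on the log2 scale in other probe sets), CAMKMT, CRYGB, FAM111A and ZNF385B (5.15-fold). The further lower genes were ERI2 (11.7-fold), DCBLD2 (9.97-fold), the glutathione transferase GSTO1 (9.44-fold), the phosphatase DUSP23, TRIM4, NPTX2 and CREB3L4 (6.93-fold). Other probe sets above background gave, none of them called, 0.24 for VSTM2A, 0.02 for FAM111A, 0.30 for DCBLD2 and −0.19 and 0.24 for TRIM4.

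No list differed between ORMES-9 and rPESC-2 by camera, the lowest adjusted p being 0.14 for cell cycle genes, of which TYMS was lower (−1.41, SE 0.08). Of the paternally expressed genes, MEST was called higher (list adjusted p = 0.9; 1 higher and 1 lower adjusted over the list alone). It lost its call without ORMES-9 replicate A (4.48), B (4.41) or C (4.54) or rPESC-2 replicate A (3.57) or C (3.65). PRDM14 of the pluripotency list was higher (1.56, SE 0.32; list adjusted p = 0.83), but not without ORMES-9 replicate A (1.41) or B (1.52) or rPESC-2 replicate A (1.53) or B (1.48). CER1 of the endoderm list was lower (−1.19, SE 0.30; 0.75), as were MAMU-B of the antigen presentation list (−1.42, SE 0.13; 0.83) and TEK of the other skin cell list (−2.21, SE 0.21; 0.71). CER1 lost its call without ORMES-9 replicate B (−0.77) or C (−1.27) or rPESC-2 replicate A (−1.12), B (−1.33) or C (−1.13). By limma, none was called among maternally expressed (4 at an unadjusted p under 0.05, adjusted p = 0.57), matrix (5, adjusted p = 0.67), mesoderm (0, adjusted p = 0.88), neuroectoderm (1, adjusted p = 0.83), trophoblast (1, adjusted p = 0.42), DNA methylation (4, adjusted p = 0.51) and germ cell genes (1, adjusted p = 0.88). The largest of these were H19 at 0.96 (SE 0.69), FBN1 at −0.93, MSX2 at 0.56, TUBB3 at 0.75, GATA3 at 0.79 (0.07 without ORMES-9 replicate C), TET1 at 2-fold lower and PRDM1 at −0.23. Apart from the paternally expressed list, counts adjusted over the list alone were the same.

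The fibroblasts were compared with ORMES-22 as the somatic control, both being biparental. The matrix protease gene MMP3 was 494-fold higher in fibroblasts (log2 8.95, SE 0.07, adjusted p = 3.5e-15) and LUM, which encodes the proteoglycan lumican, 238-fold higher (7.90, SE 0.23, adjusted p = 4.4e-11). The pluripotency factors POU5F1 and SOX2 were 299-fold and 263-fold lower (−8.22, SE 0.17, and −8.04, SE 0.15; adjusted p = 1.5e-12 and 9.2e-13). DNMT3B, a de novo DNA methyltransferase, and LIN28B, an RNA-binding protein, were 161-fold and 159-fold lower. In limma, 9928 probe sets were called, 5688 higher and 4240 lower in fibroblasts, naming 4589 genes, with a median of −0.13 over all probe sets. The other genes of the 10 largest increases were ATP8B3 (767-fold), SERPINB2 (353-fold), FGL2, the retinaldehyde dehydrogenase ALDH1A3, EFEMP1, LGR5, TGFBI (241-fold) and CTHRC1. Both other ATP8B3 probe sets went the other way, by −0.54 and −0.93. The other large decreases were in SPP1 (382-fold), ACTC1 (235-fold), RBPMS2, PROM1, CLDN6 and FAM89A. The other FAM89A probe set went the other way, by 0.45 (adjusted p = 0.0394), under the 2-fold minimum.

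Of 18 pluripotency genes, 13 fell and 1 rose in fibroblasts against ORMES-22 (camera adjusted p = 2.3e-05, and adjusted p = 0.12 with an estimated correlation). The one that rose was NANOG, at 9.53 against 8.41, and it is uncertain because NANOG has near-identical processed copies in primate genomes. Of 23 fibroblast and matrix genes, 17 rose and 1 fell (adjusted p = 9.2e-06, and adjusted p = 0.28 with an estimated correlation), among them S100A4 (log2 6.53), FAP (5.93) and COL1A2 (5.56). Of 14 antigen presentation genes, 6 rose, led by TAPBP (3.58), PSMB8 (3.21), MAMU-B (1.69) and TAP1 (1.31), with an adjusted p = 0.00097 and an adjusted p = 0.068 with an estimated correlation. Of 16 cell cycle genes, 9 fell, led by CCNE1 (−3.03), MCM3 (−2.81), MCM2 (−2.57) and AURKB (−2.10), with an adjusted p = 4e-04 and an adjusted p = 0.28 with an estimated correlation. Of 10 DNA methylation genes, 5 fell (camera adjusted p = 0.14, fry adjusted p = 7.3e-08), among them TET1 (−5.40), DNMT3A (−5.34), MBD2 (−5.25) and TRIM28 (−2.43).

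Among paternally expressed imprinted genes, 2 were higher in fibroblasts than in ORMES-22, SGCE (log2 4.34) and DIRAS3 (3.52), and 5 were lower, MEST (−4.09), SNRPN (−2.29), PEG3 (−2.28), DLK1 (−2.15) and MAGEL2 (−1.89; list adjusted p = 0.82). Camera placed this list lower and fry higher. Of maternally expressed genes, 5 were higher and 1 was lower (adjusted p = 0.62), with a median of −0.14 and a mean of 0.42. Endoderm genes held 1 higher, GATA6 (3.44), and 2 lower, APOA1 (−3.53) and CER1 (−1.60; adjusted p = 0.58). Mesoderm genes held 1 higher, MSX1 (4.00), and 5 lower, led by ACTC1, EOMES (−2.79) and MIXL1 (−1.45; camera adjusted p = 0.34, fry adjusted p = 0.00023). Trophoblast genes held 1 higher, TFAP2A (2.09), and 3 lower, the keratin KRT8 (−5.01), GATA3 (−1.92) and TEAD4 (−1.05; adjusted p = 0.99). GATA3 lost its call without ORMES-22 replicate C (−1.21) or fibroblast replicate A (−1.85), and TEAD4 without ORMES-22 replicate C (−0.80). GFAP was the 1 neuroectoderm gene called (−1.54; adjusted p = 0.58), KIT (−2.98) and MAEL (2.38-fold higher) the 2 germ cell genes (adjusted p = 0.82), and TEK (−5.05) and the endothelial adhesion gene PECAM1 (1.42) the 2 of the other skin cell list (adjusted p = 0.82). Counts adjusted over the list alone were the same for every list in this comparison. Of 11 Y-linked genes, 1 was measured, the testis-determining gene SRY, at 5.43 in the male fibroblasts and 6.16 in the female ORMES-22 cells (−0.73, SE 0.13). SRY is not a marker of fibroblasts, and no Y-linked gene expressed throughout the body was named on the array, so the sex labels were left unchecked. None of the 4 X inactivation transcripts listed was measured.

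Each ES line was last compared with the mean of the other 2, so that the biparental line could be read beside the others. SNRPN was 126-fold higher in ORMES-22 than in the mean of the parthenogenetic lines (log2 6.97, SE 0.10, adjusted p = 4.1e-12). PLAGL1 (3.21, SE 0.39, and 3.96 without ORMES-22 replicate A), PEG3 (2.54, SE 0.20), MAGEL2 (1.84, SE 0.24) and SGCE (1.34, SE 0.18) were higher too. In limma, 591 probe sets were called for ORMES-22 (238 higher, 353 lower; 308 genes), 424 for rPESC-2 (257 and 167; 216 genes) and 552 for ORMES-9 (287 and 265; 287 genes). Without ORMES-22 replicate A the counts for ORMES-22, rPESC-2 and ORMES-9 were 1136, 690 and 616.

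For ORMES-22 against that mean, 5 paternally expressed genes were higher (6 adjusted over the list alone) and none lower (camera adjusted p = 9.2e-06, and adjusted p = 0.022 with an estimated correlation). No maternally expressed gene was called by limma (6 at an unadjusted p under 0.05, adjusted p = 0.3). Of endoderm genes, 4 were lower (SOX17 −2.64, GATA6 −2.46, FOXA2 −2.11 and CER1 −1.61), with an adjusted p = 0.00022, an adjusted p = 0.28 with an estimated correlation and 0.076 without both arrays that stood apart, ORMES-22 replicate A and rPESC-2 replicate B. Of matrix genes, 4 were higher (5 adjusted over the list alone), TWIST1 (2.23), LOX (1.98), COL6A3 (1.47) and LGALS1 (1.26), with an adjusted p = 9.2e-06 and an adjusted p = 0.28 with an estimated correlation. LGALS1 lost its call in 7 of the 9 fits without 1 ES array (0.84 to 1.30), all but those without ORMES-22 replicate C or rPESC-2 replicate A, and LOX without ORMES-22 replicate B (1.65) or C (1.59), and LOX was 2.71 without ORMES-22 replicate A. GDF3 was lower (−1.26, but −0.98 and not called without ORMES-22 replicate C). The pluripotency list had a camera adjusted p = 0.18, 0.016 without ORMES-22 replicate B, and 0.77 with an estimated correlation over all arrays. KIT was lower too (−1.51, germ cell list adjusted p = 0.82), while TEK was higher (1.19, other skin cell list 0.58). ACTC1 was higher (2.36) and EOMES lower (−1.05; mesoderm list 0.81; 2 higher and 1 lower adjusted over the list alone), and EOMES lost its call in 7 of the 9 fits without 1 ES array (−1.16 to −0.62), all but those without ORMES-22 replicate B or ORMES-9 replicate B. By limma, none was called among neuroectoderm (2 at an unadjusted p under 0.05, adjusted p = 0.82; 1 adjusted over the list alone), trophoblast (5, adjusted p = 0.31), antigen presentation (8, adjusted p = 0.58), cell cycle (3, adjusted p = 0.58) and DNA methylation genes (0, adjusted p = 0.58). In the lists where no other count is given, that adjusted over the list alone was the same.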

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

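The 4-fold tests of mixed RNA and the fibroblast test for MEST, the spiked-in control test and both tests of other probe sets of named genes were chosen after the result was seen.

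The parthenogenetic lines differed from each other, by limma's test of the difference itself, in 21 of the genes named against ORMES-22. Lower in ORMES-9 than in rPESC-2 (log2) were TMEFF2 (−5.19), CAVIN2 (−4.66), RWDD3 (−4.28), ERI2 (−3.54), DCBLD2 (−3.32), TEK (−2.21), GZMA (−1.90), MRPL54 (−1.70), MAMU-B (−1.42), TYMS (−1.41), CER1 (−1.19) and DKK1 (−1.07). Higher in ORMES-9 were WFDC2 (1.03), RAB25 (1.42), PRDM14 (1.56), LIPA (1.78), SPATS2L (3.01), MECOM (3.03), VSTM2A (3.35), MEST (4.47) and THBS1 (4.61). CER1, PRDM14 and MEST each lost the call in some fits without 1 array (−1.33 to −0.77, 1.41 to 1.53 and 3.57 to 4.54), and MEST was 6.20 without rPESC-2 replicate B. With 3 arrays per group, no single array was tested as an outlier.

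The paternally expressed gene MEST was 8.95 in rPESC-2 replicate B and 3.71 and 3.86 in replicates A and C, while SNRPN stayed at 5.66 and THBS1 at 5.73 in replicate B. MEST was also high in all 3 arrays of ORMES-9, analysed as parthenogenetic too (9.97, 10.12 and 9.85). High MEST was therefore not confined to 1 array among the parthenogenetic lines. Cells or RNA of another line, at a share of 0.484 of the ORMES-9 or 0.347 of the ORMES-22 level of MEST, would raise other genes of that line alike. Over genes at least 8-fold higher in the other line, a test written before its result left both lines undecided (median share −0.00629 for ORMES-9, 3 genes, upper quartile 0.636, and −0.00102 for ORMES-22, 7 genes, upper quartile 0.494). Over genes at least 4-fold higher, chosen after that, the median shares of 0.0162 (upper quartile 0.106) and −0.00272 (upper quartile 0.0962) over 18 genes each argue against either line as the source, and macaque fibroblast RNA is argued against by their highest MEST level of 6.51. ZNF22 (8.75 against 4.37 and 5.83) and PFKP (10.46 against 6.26 and 7.69) were also high in replicate B, and a difference between cultures, such as their passages (10 against 16), or mouse feeder RNA may be a source and was not tested.

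ORMES-22 replicate A stood apart from replicates B and C, with an array weight of 0.371 against 0.749 to 1.73 for the other arrays. Spiked-in control signal is argued against as the cause, since the ORMES-9 arrays varied about as much in it (a range of 0.71 against 0.79 in ORMES-22) and still correlated at 0.9948 or more. Parthenogenetic cells or RNA in replicate A stay open: over 7 genes at least 8-fold higher in both parthenogenetic lines, the median share was 0.0852 (upper quartile 0.159), with SH3YL1 at 0.33 and GCA at −0.000825. Fewer cells of other types stay open too, since 2 of 5 lists of other cell types were lower in replicate A by more than 2 standard errors (endoderm −0.29, trophoblast −0.36) and 0 were higher. A difference between cultures of the line may also be the source, and was not tested.

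Very large differences between ES lines of outbred animals could come from a sequence variant under the probes of a single probe set. The 60 largest differences named between ES lines fell on 43 genes. In 10 of these genes, 18 other probe sets had a mean above a log2 signal of 6 in an ES line, and 15 of them (83.3%) were called in the same direction in every comparison that named the gene, while of all 28 other probe sets above the background of 4.26, in 17 genes, 16 were (57.1%, exact 95% interval 37.2 to 75.5, probe sets of 1 gene not being independent). For the 10 genes with at least 1 such called probe set, among them SNRPN, DCTD, THBS1 and CAVIN2, this argues against a variant as the whole cause. It stays open for the 7 genes with none (DCBLD2 with 0.24 and 0.30, WFDC2 with −0.11, SOX17 with 0.70, TRIM4, VSTM2A, CSGALNACT2 and FAM111A) and for 26 genes without another probe set above background, such as DERA, GCA and AKAP7, while parental origin or other inherited variation between the lines stays open throughout, untested.

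Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. In each pairwise comparison only the real split (1 of 10) gave as many called probe sets, 332 for rPESC-2 against ORMES-22, 566 for ORMES-9 against ORMES-22, 689 for ORMES-9 against rPESC-2 and 9897 for fibroblasts against ORMES-22, and the highest of the other splits gave 0. For the 9 ES arrays, 100 splits into 3 groups of 3 were counted, and a chance assignment of single arrays to groups can be excluded for each of the following. At most 1 of the drawn splits kept the lines whole. The splits therefore show that arrays differ by line and cannot test parental origin, which sets apart 1 line. For ORMES-22 against the mean of the others 2 splits gave as many (real value 486, highest other 499), for rPESC-2 2 (357, highest other 499), for ORMES-9 1 (499, highest other 354) and for the sharing between parthenogenetic lines 2 (208, highest other 239). Those highest others of 499 and 239 are the same 3 lines exchanged, which points to a structure of the samples by line and leaves open whether a count is tied to parental origin. Without ORMES-22 replicate A the sharing was 654, and 273 and 248 with the lines exchanged, but without ORMES-22 replicate B it was 211, and 154 and 276. The order of the lines thus depended on the array left out. For paternally expressed genes higher in ORMES-22, 1 split gave as many (5, highest other 0), which again sets apart 1 line and does not test parental origin.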

How the results depend on the processing

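The alternative without both arrays that stood apart and those of the sharing with exchanged lines were chosen after seeing the data. For named genes, 1555 of 1656 values with 1 array left out stayed on their side of the threshold in the same direction, 80 became weaker, 21 stronger and 0 reversed. Under the other alternatives 2315 of 2419 stayed, 80 became weaker, 23 stronger and 1 reversed. The reversed one was SNRPN in fibroblasts, 2.36 against the mean of the 3 ES lines, because that mean includes the parthenogenetic lines. Of list tests, 422 of 429 with 1 array left out and 807 of 832 otherwise stayed on their side. The order below is rPESC-2, ORMES-9 (each against ORMES-22), ORMES-9 against rPESC-2, fibroblasts, ORMES-22, rPESC-2 and ORMES-9 (each against the mean of the others), and shared probe sets. With no fold minimum the counts were 2536, 3158, 2753, 29377, 3101, 2511, 3178 and 949, and with at least 3-fold 207, 288, 209, 5507, 175, 132, 174 and 98. In genes they were 262, 335, 240, 3752, 241, 165, 217 and 123, since fewer features were tested. With 1 array left out they ranged over 460 to 1493, 717 to 1284, 542 to 666, 9656 to 10280, 482 to 1136, 334 to 690, 511 to 616 and 211 to 654, the highest for comparisons with ORMES-22 among ES lines being without ORMES-22 replicate A. Without both arrays that stood apart, they were 1286 for rPESC-2, 1284 for ORMES-9, 1057 for ORMES-22 against the mean and 609 shared, against 227 and 262 with rPESC-2 and ORMES-9 in the place of ORMES-22. With 1 array left out, those exchanged counts ranged over 142 to 273 and 241 to 277. With only the groups compared, rPESC-2 had 332, ORMES-9 566, ORMES-9 against rPESC-2 689 and fibroblasts 9897 (656, 831, 650 and 9928 in the main fit). In these fits 146 were shared, and 2 paternally expressed genes were lower in rPESC-2 and 2 in ORMES-9. All of them leave fewer arrays to estimate the spread, yet of these pairwise counts only those of a parthenogenetic line against ORMES-22 fell much. ORMES-22 had the widest median spread within a group (SD 0.127, others 0.0961 to 0.11), and the cause was not tested. Array weights gave 1006 for rPESC-2. ORMES-22 replicate A had the lowest weight (0.371), and leaving it out moved the count the same way, to 1493. The part of the other weights was not tested. Without dim probe sets, 3 paternally expressed genes were lower in ORMES-9 and 3 higher in ORMES-22 against the mean, since fewer genes were tested. With 1 array left out, 5 to 6 of that list were lower in rPESC-2, 4 to 5 lower in ORMES-9 and 5 to 6 higher in ORMES-22 against the mean. Over all 4 groups the letters A, B and C did not pair the arrays: same-letter correlations of deviations ran from −0.306 to 0.265, 6 of 18 over 0.1, and 4 of 12 arrays correlated best with their own letter. Spiked-in control signal, however, ran alike by letter in ORMES-22 (10.58, 10.23 and 9.79) and ORMES-9 (10.54, 10.18 and 9.82). Deviations of these lines correlated at 0.189 for A, −0.0603 for B and 0.265 for C. Pairs of arrays with different letters ran from −0.251 to 0.35 over all groups. The highest was ORMES-22 replicate A with rPESC-2 replicate B, both arrays that stood apart. A batch shared by some of the arrays, within or across letters, stays possible, and a block by letter over all groups does not test it. With the letter as a block, the counts were 631, 821, 639, 9927, 581, 417, 542 and 262. The cell cycle list in rPESC-2 then had an adjusted p = 0.046, against 0.034 to 0.77 over all alternatives, and DLK1 was not called. Signal over background limits genes whose means lie under 4.26.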

Other observations

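The genes of the next paragraph and the chromosome followed up were chosen after the result was seen, while the tests of the scan and of the chromosome's blocks were set before theirs.

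Beside SOX17 and GATA6, a few single genes called in both parthenogenetic lines against ORMES-22 are given here as examples, with no claim about the groups they belong to. The homeobox gene GSC was 5.72 in ORMES-22, 8.20 in rPESC-2 and 7.86 in ORMES-9 (log2 means, n = 3), the chemokine receptor gene CXCR4 6.31, 7.88 and 7.72, and FGF17 5.49, 7.02 and 7.07. The junction protein gene F11R was at 10.87, 12.36 and 12.01, the transcription factor gene OVOL2 at 7.00, 8.13 and 8.89, the protease gene PRSS8 at 7.95, 9.01 and 9.45 and the receptor gene ERBB3 at 7.23, 8.62 and 8.96. Lower in both lines were the signalling factor gene WNT5A at 9.08, 7.63 and 8.02, FOXF2 at 6.26, 4.26 and 4.39 and VGLL3 at 8.30, 7.04 and 7.05. In fibroblasts WNT5A was 11.49, FOXF2 8.08 and VGLL3 11.85, and F11R was 6.20. The keratin gene KRT8 was not called between ES lines, and of the fibroblast and matrix list 3 of 23 genes fell in rPESC-2 and 2 of 23 in ORMES-9.

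A paternally expressed gene that is active in both ES cells and fibroblasts would be high in ORMES-22 and fibroblasts and low in both parthenogenetic lines. A scan by this rule misses genes at background in fibroblasts, such as PEG3 (mean 3.97) and MAGEL2 (4.10), both called lower in the parthenogenetic lines. The scan found 19 genes of that kind, against 11 for rPESC-2 and 8 for ORMES-9 in the place of ORMES-22 (one-sided exact binomial p = 0.1 against the higher). Of the 19, SNRPN, PLAGL1 and SGCE are on the imprinted lists. In the mirrored direction there were 31, 8 and 22. A number of this size may arise from differences between any 3 lines, and the 16 others, such as CSGALNACT2, FOXF2 and TWIST1, cannot be told apart from such differences, because there is 1 biparental line.

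In ORMES-22 replicate A, genes of a single chromosome were shifted upward together. Over 296 genes of the chromosome that carries EFEMP1 and EIF2AK3, the median difference from the other replicates was 0.257, against 0.0358 for all genes, and 69.9% lay above the median of all genes. The excess over the median of all genes, 0.221, was the largest of 252 combinations of array and chromosome looked at, the next being an excess of 0.145 for another chromosome in ORMES-22 replicate C. None of 10000 random sets of as many genes lay as far (highest 0.128). The random sets do not keep genes of a chromosome together, and the chromosome had been picked as the largest excess. They therefore do not measure how rare such a shift is. Of 10 consecutive blocks, 9 lay above the median of all genes, but the block from CNOT11 did so by little (0.0368) and that from MAL lay at −0.0125, while the 8 blocks from EIF2AK3 to RDH14 lay between 0.203 and 0.434. A gain of most of the chromosome in part of the cells of that culture is a candidate explanation, and a gain of all of it is less well matched by the blocks from MAL and CNOT11. Whether DNA copy number differed was not measured here.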
